A study of Homo sapiens with 29 samples.

How the data were processed

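The samples were total RNA libraries of C4-2 and 22Rv1 cells, prepared with a stranded total RNA kit that removes ribosomal RNA. The deposited values were raw counts per Ensembl feature, in 1 table for each cell line, each with 63677 features in the same order. Per the submitters' processing notes, reads were aligned to hg19 with STAR 2.5.2a and counted with featureCounts 1.5.0-p3, and the authors tested differences with DESeq2 1.14.1. The annotation release, the strand setting and the handling of reads with several alignments are not given in the sources used here. Every value was a whole number, all 29 columns of values matched a sample, and 5904 features on patches, haplotypes or unplaced scaffolds held 0 reads. Gene names and types were taken from GENCODE for 52526 features, which held 91.0% to 97.0% of the counts of a library. Positions are those of hg19 as far as the files give them.

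Total counts lay between 29.58 M and 44.86 M per C4-2 library and between 31.61 M and 44.91 M per 22Rv1 library. Counts of replicates spread beyond counting error, with a lowest chi-square per degree of freedom of 4.01 between 2 libraries of a group, so that the spread between libraries and not the depth set the precision of abundant genes. Shares of counts that went to 7SK, mitochondrial RNA, lincRNA and other classes were computed for each library.

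Groups were taken from the sample titles. The C4-2 libraries were fitted together with 1 coefficient per group, the 22Rv1 libraries apart, and the C4-2 Ctrl and CC-115 libraries with the 22Rv1 libraries for the difference between lines. Genes were kept by filterByExpr (22860 in C4-2, 19392 in 22Rv1 and 22922 in the joint fit), scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with robust dispersions. Adjusted p-values are Benjamini-Hochberg values over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Standard errors of single genes were the absolute log2 fold change divided by the square root of F. The comparisons were each compound and combination against Ctrl, each combination against Enza and against its inhibitor alone, the interaction of each inhibitor with Enza, the inhibitors against each other, CC-115 against Control in 22Rv1, and the difference of the CC-115 effect between the lines. The scripts used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

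The comparisons, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined. There were 22 gene lists with 394 genes, of which 384 had an identifier in the tables. They were androgen response, androgen-repressed genes, DNA replication and G1/S, mitosis and G2/M, replication-dependent histones, p53 targets, non-homologous end joining, homologous recombination and Fanconi, ATF4 and amino acid supply, sterol synthesis, fatty acid synthesis, glycolysis and hypoxia, FOXO targets and receptor feedback, lysosome and autophagy, ribosome biogenesis and MYC, translation machinery, Wnt signalling, epithelial-mesenchymal transition, interferon response, nuclear oxidative phosphorylation, neuroendocrine markers, and stromal, immune and endothelial markers. Each was tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Camera compares a list with all other genes. The median of a list was taken over its measured members.

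The named genes were PRKDC, MTOR and KLK3 in every comparison, whatever their values, the 6 largest rises and 6 largest falls of each single compound and the 3 largest in each direction of the other comparisons. These were taken among called protein-coding genes with an approved symbol and an average log2 CPM of at least 1, with every library of the first group on the same side of every library of the second, a condition dropped for interactions. For each list that camera called or that had at least 0.25 of its measured members called, up to 4 called members with the largest change were added, and the text names a subset of these, taking the largest first within a list and direction. Some genes that these rules select are not reported here. CDT1 in 22Rv1 was named after its value was seen, as the single replication gene that rose.

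Overlaps of calls were compared with the product of the call counts divided by the genes tested. For pairs of comparisons with the same Ctrl libraries, 100 simulations drew Ctrl libraries and unchanged groups around the Ctrl means. They gave the correlation and covariance that shared controls produce when no gene changes. They cannot bound the overlap that shared controls add where many genes are called. The method was tested on simulated data with 200 changed genes. In a simulated comparison of NU7441 with Ctrl it recovered 32.8%, 61.2% and 89.4% of genes changed 1.5-fold, 2-fold and 4-fold and called 2 of 21948 unchanged genes. In 22Rv1 the shares were 1.49%, 43.3% and 83.3%, with 10 of 18728 unchanged genes called. For the CC-115 interaction with Enza they were 13.4%, 52.2% and 81.8%, and for the difference between lines 2.99%, 43.3% and 75.8%.

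Whether replicate numbers pair libraries across groups was checked in the residuals. The mean correlation of residuals was −0.0195 between libraries with the same number and 0.00957 between libraries with different numbers, so the replicate number was not a term of the fit. The alternatives were median-of-ratios size factors, DESeq2 1.42.0 as a whole, no filter, a stricter filter (CPM of at least 1 in 3 libraries, or in 2 in 22Rv1), small and mitochondrial RNA removed, a log2 fold change of at least 1, a replicate block, a fit of only the groups compared, each replicate left out in turn, camera with an estimated correlation and fry for the lists, and an adjusted p under 0.01 for the overlaps. After the libraries were seen, 2 alternatives were added: leaving out both libraries that stood apart (Enza 1 and CC-115+Enza 1), and a term for the shallower 22Rv1 libraries (Control 3 and CC-115 2).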

Results

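RNA was sequenced from 29 libraries of 2 human prostate cancer cell lines. C4-2 is a castration-resistant derivative of LNCaP, and 22Rv1 comes from a relapsed xenograft. In C4-2 there were 8 groups of 3 libraries: untreated (Ctrl), NU7441, CC-115, CC-223, enzalutamide (Enza), and each of the first 3 compounds together with Enza. In 22Rv1 there were 3 Control and 2 CC-115 libraries. Per the labels each compound was given at 1 µM for 24 h. NU7441 and CC-115 carry the label of DNA-PK inhibition, CC-223 that of a TOR kinase inhibitor and Enza that of an antiandrogen. CC-115 is known as an inhibitor of both DNA-PK and TOR kinase. Total counts per library lay between 29.58 M and 44.86 M in C4-2 and between 31.61 M and 44.91 M in 22Rv1. By group they were 34.15 to 36.57 M in Ctrl, 32.74 to 39.18 in NU7441, 34.94 to 38.56 in CC-115, 29.58 to 33.5 in CC-223, 30.49 to 36.42 in Enza, 35.49 to 42.38 in NU7441+Enza, 31.35 to 44.86 in CC-115+Enza and 33.91 to 39.77 in CC-223+Enza. The 22Rv1 Control libraries held 31.61 to 43.57 M and the CC-115 libraries 31.77 and 44.91 M.

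The series asks how inhibition of DNA-PK changes transcription. KLK3 (ENSG00000142515, chromosome 19, 51358171 to 51364020 in hg19), which encodes prostate-specific antigen, stood at 1928 ± 81.1 TMM-scaled CPM (mean ± SD, n = 3) in Ctrl, 2305 ± 130 with NU7441, 4369 ± 71.4 with CC-115, 3252 ± 60 with CC-223 and 639 ± 57.5 with Enza. With Enza added it stood at 602 ± 22.7, 1318 ± 237 and 1125 ± 8.32 CPM for NU7441, CC-115 and CC-223. PRKDC (ENSG00000253729, chromosome 8, 48685669 to 48872743), which encodes the catalytic subunit of DNA-PK, fell from 1104 ± 13 to 757 ± 5.62 CPM with CC-115 in C4-2 and from 433 ± 31 (n = 3) to 171 ± 9.57 (n = 2) in 22Rv1. MTOR (ENSG00000198793, chromosome 1, 11166592 to 11322564) rose from 197 ± 3.43 to 357 ± 20.2 CPM with CC-115 in C4-2.

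**Figure D1:**
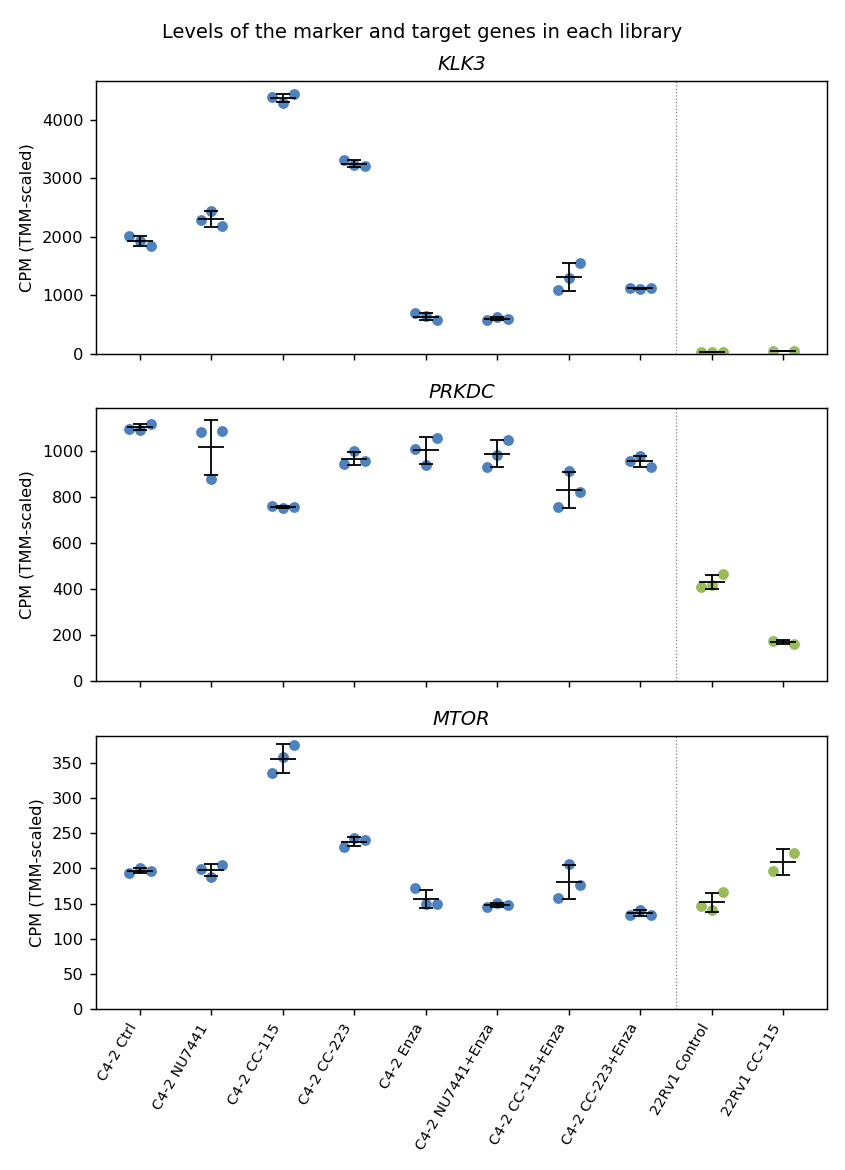
Level of KLK3, PRKDC and MTOR in each library (vertical axis, TMM-scaled CPM, 22Rv1 scaled separately from C4-2), with the mean and SD of each group. All 3 CC-115 libraries of C4-2 lie above all 3 Ctrl libraries for KLK3 and MTOR and below them for PRKDC.

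NU7441 against Ctrl asked what the DNA-PK inhibitor did alone. ACTA2 (ENSG00000107796, chromosome 10, 90694831 to 90751147), smooth muscle actin, fell by 1.94 ± 0.17 on the log2 scale (log2 fold change ± SE throughout, n = 3 libraries per C4-2 group). UGT2B11 (−1.68 ± 0.18), UGT2B15 (−1.36 ± 0.19) and UGT2B17 (−1.34 ± 0.21), which encode glucuronosyltransferases, also fell. So did the interferon-inducible GTPase GBP2 (−1.46 ± 0.20) and CCDC141 (−1.26 ± 0.20). HTRA1, a secreted serine protease (ENSG00000166033, 1.24 ± 0.15, adjusted p = 4.26e-05), CAMK2B (1.24 ± 0.20), PBXIP1 (1.23 ± 0.19), TCP11L2 (1.45 ± 0.25), AHNAK2 (1.45 ± 0.28) and ZMYND12 (1.35 ± 0.29) rose. Of 25 measured mitosis and G2/M genes 15 fell and 25 fell adjusted over the list alone, with a median of −0.61 (camera adjusted p = 3.84e-20, adjusted p = 0.278 with an estimated correlation). The mitotic kinases AURKA (−0.86 ± 0.19) and PLK1 (−0.84 ± 0.17) fell. None of the 31 DNA replication genes was called, and 11 fell adjusted over the list alone (median −0.31, camera adjusted p = 9.14e-11, adjusted p = 0.278 with an estimated correlation).

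Smaller shifts were called with NU7441 in metabolic lists. Of 21 sterol synthesis genes 4 rose and 12 rose adjusted over the list alone (median 0.30, camera adjusted p = 4e-06, adjusted p = 0.278 with an estimated correlation). Of 12 FOXO and receptor feedback genes 4 rose and 6 rose adjusted over the list alone, among them KLHL24 (1.20 ± 0.19, camera adjusted p = 8.23e-05 for the list, adjusted p = 0.1 with an estimated correlation). CHAC1 (ENSG00000128965), a glutathione-degrading ATF4 target, fell by 1.03 ± 0.15, and 2 of 26 ATF4 and amino acid supply genes fell (3 adjusted over the list alone, camera adjusted p = 1.36e-05, adjusted p = 0.278 with an estimated correlation). KLK3 (0.26, adjusted p = 0.233), PRKDC (−0.12, 0.614) and MTOR (0.00, 0.99) were not called.

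In all, 522 genes rose and 254 fell with NU7441 among 22860 tested, by edgeR at an adjusted p under 0.05, so that 67.3% of calls were rises. That majority was not stable: the share was 56.8% with small and mitochondrial RNA removed, 45.2% in a fit of only these 6 libraries, 48.1% without NU7441 1 and 48% without Enza 1 and CC-115+Enza 1. The count rested on single libraries: it was 162, 254 or 361 without Ctrl 1, 2 or 3 and 76 without NU7441 2. It was 2706 in a fit of only these 6 libraries, 1198 with DESeq2 and 1287 with a stricter filter. Without Enza 1 and CC-115+Enza 1, which stood apart from their groups, it was 5011. Those libraries are in neither group compared here and enter only through the spread, filter and scaling of the shared fit. Without NU7441 2 the calls of PLK1 (−0.59, adjusted p = 0.0651), AURKA (−0.64, 0.151), AHNAK2 (1.11, 0.118) and ZMYND12 (0.89, 0.239) ended, and the values of KLHL24 (0.77) and TCP11L2 (0.86) were smaller. Calls also ended without Ctrl 1 for AURKA (adjusted p = 0.0766) and AHNAK2 (0.055) and without Ctrl 3 for ZMYND12 (0.0678).

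CC-115 against Ctrl asked what the compound with both targets did alone, and it changed the most genes of the single compounds. All 31 measured DNA replication and G1/S genes fell, with a median of −2.89 (camera adjusted p = 1.37e-24, adjusted p = 0.121 with an estimated correlation). CLSPN (ENSG00000092853, chromosome 1, 36185819 to 36235568), which encodes the checkpoint mediator claspin, fell by 4.53 ± 0.15, from 74.9 ± 2.58 to 3.24 ± 0.113 CPM. MCM10 (−4.46 ± 0.18) and DTL (−3.81 ± 0.15), both of the replication fork, and the transcription factor E2F2 (−4.63 ± 0.20) fell in like measure. All 7 measured replication-dependent histone genes, of 16 in the list, fell (median −2.46, camera adjusted p = 1.82e-05, adjusted p = 0.266 with an estimated correlation), with H1-5 at −4.0 ± 0.26. All 16 homologous recombination and Fanconi genes fell (median −1.71, camera adjusted p = 7.35e-11, adjusted p = 0.121 with an estimated correlation), among them the exonuclease EXO1 (−2.83 ± 0.17) and the recombinase partner RAD54L (−2.39 ± 0.14). Of 25 mitosis genes 23 fell (median −1.14, camera adjusted p = 1.56e-06, adjusted p = 0.458 with an estimated correlation), with CDK1 at −2.28 ± 0.20 and CCNA2 at −1.88 ± 0.19.

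Androgen response genes moved the other way with CC-115. Of 30 measured 20 rose and 5 fell (median 0.66, camera adjusted p = 0.000246, adjusted p = 0.121 with an estimated correlation). KLK2 rose by 2.29 ± 0.13, the membrane protease TMPRSS2 by 1.59 ± 0.12 and KLK3 by 1.18 ± 0.12 (adjusted p = 2.63e-09). MTOR rose (0.86 ± 0.10) and PRKDC fell (−0.54 ± 0.10, adjusted p = 7.15e-05). Of the 6 androgen-repressed genes 1 rose and 3 fell (median −0.33, camera adjusted p = 0.389). Of 12 FOXO and receptor feedback genes 10 rose and 2 fell (camera adjusted p = 0.00283, adjusted p = 0.121 with an estimated correlation), with the adaptor IRS2 at 3.42 ± 0.16 and the ubiquitin ligase FBXO32 at 3.30 ± 0.15. Outside the lists, DMGDH, a mitochondrial dehydrogenase of choline breakdown (ENSG00000132837, 4.64 ± 0.18), TCP11L2 (4.35 ± 0.23), ZMAT1 (3.75 ± 0.24), TECTA (3.37 ± 0.27) and the secreted glycoprotein RELN (3.32 ± 0.14) were among the largest rises. BRDT (ENSG00000137948, −5.84 ± 0.33), a testis bromodomain protein, RPP25 (−5.46 ± 0.33), FAM111B (−4.63 ± 0.19), the kinase MAP2K6 (−5.45 ± 0.15) and the peptide hormone APLN (−5.22 ± 0.18) were among the largest falls.

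Energy and immune lists fell in part with CC-115. Of 18 nuclear oxidative phosphorylation genes 15 fell (median −0.74, camera adjusted p = 5.24e-05, adjusted p = 0.458 with an estimated correlation), with cytochrome c (CYCS) at −1.42 ± 0.18. Of 15 glycolysis and hypoxia genes 10 fell and 1 rose (camera adjusted p = 0.002, adjusted p = 0.333 with an estimated correlation), with the prolyl hydroxylase EGLN3 at −1.74 ± 0.12 and lactate dehydrogenase LDHA at −1.69 ± 0.15. Of 14 interferon response genes 9 fell and 2 rose (camera adjusted p = 0.0234, adjusted p = 0.333 with an estimated correlation), with OAS1 at −3.47 ± 0.51. Of 15 Wnt genes 8 fell and 2 rose (camera adjusted p = 0.015, adjusted p = 0.121 with an estimated correlation). Of 19 ribosome biogenesis genes 13 fell and 1 rose (camera adjusted p = 0.0234, adjusted p = 0.759 with an estimated correlation).

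The remaining lists were not called by camera with CC-115, and their members went both ways. Of 26 ATF4 genes 5 rose and 9 fell (adjusted p = 0.349, the median of 0.03 and the test differed in sign), with the TOR regulator DDIT4 at −3.17 ± 0.18 and the stress factor DDIT3 at 2.37 ± 0.18. In the sterol list 6 rose and 9 fell of 21 (0.334), and in the fatty acid list 2 rose and 4 fell of 11 (0.408). In the end joining list 4 rose, among them POLM (1.85), and 6 fell, among them XRCC5 (−1.03), of 12 (0.764). Among p53 targets 5 rose, among them GDF15 (1.71), and 10 fell, among them FAS (−2.55), of 20 (0.133). In the lysosome list 8 rose and 5 fell of 21 (0.296), and in the list of translation machinery 5 rose and none fell of 18 (0.296). In the epithelial-mesenchymal list 4 rose and 5 fell of 11 (0.972, the median of −0.21 and the test differed in sign). Of 4 neuroendocrine markers 1 rose and 2 fell (0.682), and of 4 stromal, immune and endothelial markers 1 fell (0.713). In all, 6310 genes rose and 5945 fell.

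CC-223 against Ctrl asked what TOR kinase inhibition did alone. Of 30 androgen response genes 26 rose and 28 rose adjusted over the list alone, with a median of 0.78 (camera adjusted p = 1.14e-20, and 0.000159 with an estimated correlation). STEAP4, a metalloreductase (ENSG00000127954, 2.5 ± 0.22), NDRG1 (1.87 ± 0.12), TMPRSS2 (1.74 ± 0.12) and the transcription factor MAF (1.68 ± 0.11) were the largest rises of that list. STEAP4 held 21, 16 and 18 counts in Ctrl. KLK3 rose by 0.75 ± 0.11 (adjusted p = 2.85e-05), and PRKDC was not called (−0.19 ± 0.10, adjusted p = 0.191). MTOR stood at 0.28 ± 0.10 (adjusted p = 0.0391), a call that ended with every library left out (adjusted p = 0.22 without Ctrl 1, 0.151 without Ctrl 2, 0.161 without Ctrl 3, 0.133 without CC-223 1, 0.196 without CC-223 2 and 0.182 without CC-223 3). Of 26 ATF4 and amino acid supply genes 21 fell and 24 fell adjusted over the list alone (median −0.83, camera adjusted p = 2.13e-19, adjusted p = 0.0193 with an estimated correlation). CHAC1 fell by 2.87 ± 0.18, and DDIT4 (−1.44 ± 0.17), SESN2 (−1.30 ± 0.12) and the serine synthesis enzyme PSAT1 (−1.22 ± 0.12) also fell.

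All 25 mitosis genes fell with CC-223 (median −1.12, camera adjusted p = 1.14e-20, adjusted p = 0.107 with an estimated correlation), with CDC20 at −1.68 ± 0.17. Of 31 replication genes 30 fell and 31 fell adjusted over the list alone (median −0.66, camera adjusted p = 7.35e-17, adjusted p = 0.124 with an estimated correlation), with thymidine kinase TK1 at −1.02 ± 0.16 and GINS1 at −1.01 ± 0.17. All 7 measured histone genes (median −0.90, adjusted p = 0.185 with an estimated correlation) and 15 of 16 homologous recombination genes (median −0.64, adjusted p = 0.124 with an estimated correlation) fell. Of 12 FOXO and receptor feedback genes 8 rose (median 0.45, camera adjusted p = 3.68e-06, adjusted p = 0.0169 with an estimated correlation), with KLHL24 at 2.01 ± 0.20, IRS2 at 1.88 ± 0.17 and the growth factor receptor IGF1R at 1.53 ± 0.19. Of 11 fatty acid synthesis genes 5 fell (camera adjusted p = 6.72e-05, adjusted p = 0.0394 with an estimated correlation), with the elongase ELOVL6 at −1.01 ± 0.12. Of 21 sterol genes 8 fell (camera adjusted p = 4.32e-05, adjusted p = 0.217 with an estimated correlation), and of 15 glycolysis genes 8 fell (camera adjusted p = 2.19e-06, adjusted p = 0.107 with an estimated correlation). Outside the lists TCP11L2 (2.64 ± 0.23), OTULINL (1.99 ± 0.10), ABTB1 (1.99 ± 0.22), ZMAT1 (1.97 ± 0.25) and MICAL1 (1.92 ± 0.13) rose most, and LRRC31 (−2.79 ± 0.38), BRDT (−1.68 ± 0.22) and the glutamate transporter SLC1A3 (−1.66 ± 0.15) fell most. UGT2B15, of the androgen-repressed list, fell by 2.0 ± 0.20. In all, 2959 genes rose and 2497 fell, and 5188 and 4712 without Enza 1 and CC-115+Enza 1. The majority turned to falls when any 1 of the 6 libraries was left out, and with median-of-ratios size factors (2488 rises and 2935 falls), DESeq2 (2520 and 3157), a stricter filter (2658 and 3365), small and mitochondrial RNA removed (2544 and 2981) and a fit of only these 6 libraries (4355 and 5027).

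**Figure D2:**
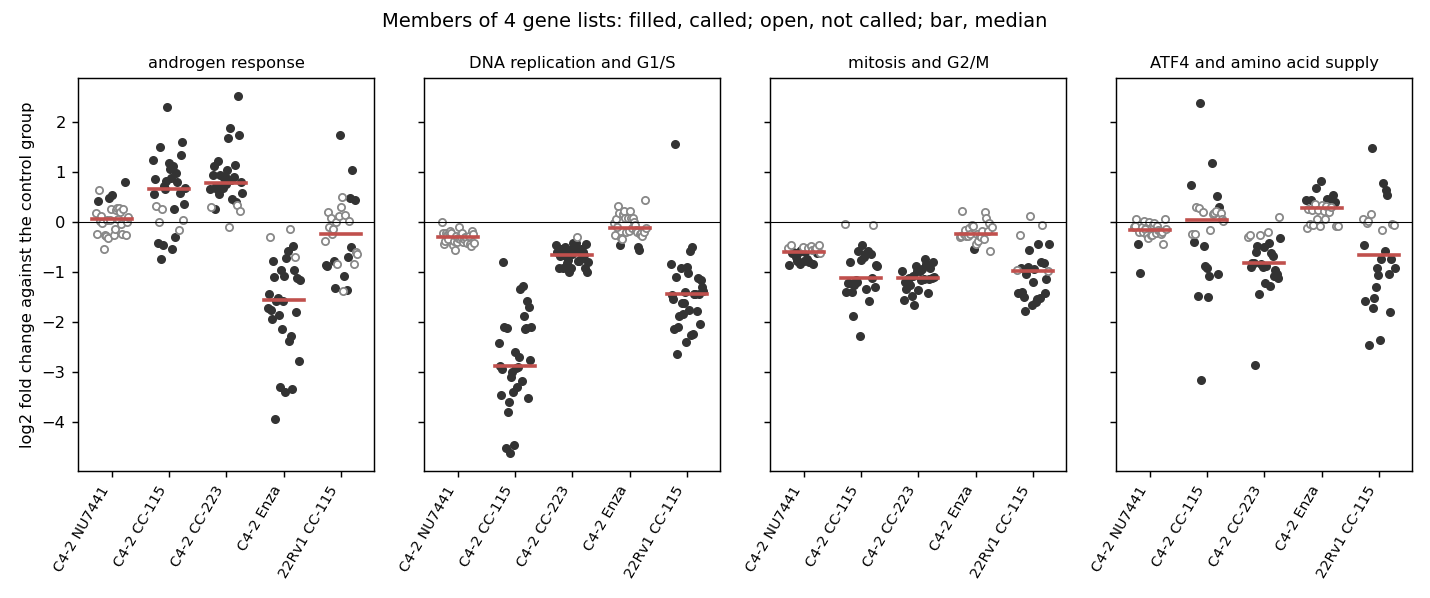
Log2 fold change against the control group (vertical axis) of the members of 4 gene lists with each single compound; filled points were called at an adjusted p under 0.05, open points were not, and bars are medians. The replication median lies at −2.89 with CC-115, −0.66 with CC-223 and −0.31 with NU7441 in C4-2, and at −1.45 with CC-115 in 22Rv1.

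The 3 compounds were set against each other at the same dose and time. Against NU7441, CC-115 gave lower replication genes in all 31 (−2.53 median, camera adjusted p = 2.41e-24, adjusted p = 0.185 with an estimated correlation), with CLSPN at −4.18 ± 0.15. Androgen response genes were higher in 21 of 30 and lower in 3 (camera adjusted p = 0.000195, adjusted p = 0.185 with an estimated correlation), with KLK2 at 2.26 ± 0.13 and KLK3 at 0.92 ± 0.12. PRKDC was lower (−0.43 ± 0.10, adjusted p = 0.0012), and MTOR was higher (0.85 ± 0.10). DMGDH (4.02 ± 0.17), POPDC2 (3.04 ± 0.18), TGFB2 (3.03 ± 0.20), RPP25 (−5.43 ± 0.33), MAP2K6 (−5.08 ± 0.15) and BRDT (−4.97 ± 0.35) differed most among genes outside the lists. In all, 5596 genes were higher and 5599 lower.

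Against CC-223, CC-115 gave lower replication genes in 30 of 31 (median −2.27, camera adjusted p = 1.34e-23, adjusted p = 0.326 with an estimated correlation), with E2F2 at −3.81 ± 0.20 and CLSPN at −3.59 ± 0.15, and lower homologous recombination genes in 15 of 16 (median −1.02, adjusted p = 0.398 with an estimated correlation). ATF4 genes were higher in 17 of 26 and lower in 2 (camera adjusted p = 2.9e-05, adjusted p = 0.52 with an estimated correlation), with DDIT3 at 2.85 ± 0.18 and the cystine transporter SLC7A11 at 1.59 ± 0.13. Mitosis genes split into 6 higher and 3 lower of 25 (camera adjusted p = 0.371). KLK3 was higher (0.43 ± 0.11, adjusted p = 0.00344), KLK2 was higher (1.38 ± 0.13) and CHRNA2 lower (−1.96 ± 0.17). MTOR was higher (0.58 ± 0.10) and PRKDC lower (−0.36 ± 0.10, adjusted p = 0.00652). The call of PRKDC ended at adjusted p = 0.0685 without CC-115 1, 0.0757 without CC-115 2, 0.0733 without CC-115 3, 0.0514 without CC-223 1 and 0.0568 without CC-223 3. Outside the lists DMGDH (4.55 ± 0.18), NPIPB6 (3.04 ± 0.24) and TECTA (3.02 ± 0.27) were highest and RPP25 (−4.92 ± 0.35), APLN (−4.62 ± 0.19) and MAP2K6 (−4.39 ± 0.15) lowest. In all, 4678 genes were higher and 5178 lower.

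NU7441 against CC-223 gave lower androgen response genes in 27 of 30 (median −0.59, camera adjusted p = 1.34e-33, and 6.55e-06 with an estimated correlation), with STEAP4 at −2.25 ± 0.22, MAF at −1.95 ± 0.11 and CHRNA2 at −1.77 ± 0.17. KLK3 was lower (−0.50 ± 0.11, adjusted p = 0.007), and MTOR (−0.27 ± 0.10, 0.0896) and PRKDC (0.07 ± 0.10, 0.761) were not called. The call of KLK3 ended at adjusted p = 0.0695 without NU7441 3 and 0.0508 without CC-223 1. Outside the lists FOXN4 (2.30 ± 0.30) and LRRC31 (1.96 ± 0.42) were highest, and CCDC141 (−1.87 ± 0.20) and OTULINL (−1.83 ± 0.10) were low. ATF4 genes were higher in 17 of 26 (median 0.56, adjusted p = 0.0104 with an estimated correlation), with CHAC1 at 1.84 ± 0.18 and DDIT4 at 1.45 ± 0.16. Sterol genes were higher in 16 of 21 (median 0.66, adjusted p = 0.0104 with an estimated correlation), with INSIG1 at 1.32 ± 0.14, and fatty acid genes in 6 of 11 (median 0.60, adjusted p = 0.000951 with an estimated correlation), with the desaturase SCD at 1.02 ± 0.11. In all, 731 genes were higher and 941 lower. The total of 1672 became 877 without NU7441 1, 934 without NU7441 3, 906, 904 and 959 without CC-223 1, 2 and 3, 4228 in a fit of only these 6 libraries, and 5823 without Enza 1 and CC-115+Enza 1.

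Calls overlapped between the inhibitors by direction. Against the shared Ctrl libraries, NU7441 and CC-115 both raised 357 genes (144.1 by chance) and both lowered 201 (66.1), with 83 called in opposite directions. NU7441 and CC-223 both raised 425 (67.6 by chance) and both lowered 193 (27.7), with 8 opposite. CC-115 and CC-223 both raised 2050 (816.8 by chance) and both lowered 2006 (649.4), with 274 opposite. Simulated groups with no change, set against simulated Ctrl libraries 100 times, gave at most 1 gene called on the same side in both. Where no gene changes almost none is called, so this count cannot bound the overlap that shared controls add to the real calls. The correlation of fold changes across genes was 0.436 for NU7441 and CC-115, 0.635 for NU7441 and CC-223 and 0.563 for CC-115 and CC-223, against simulated means of 0.512, 0.495 and 0.498 and at most 0.537, 0.524 and 0.523. The covariances, 0.173, 0.137 and 0.312, lay above the highest simulated ones (0.0612, 0.063 and 0.0619). Comparisons that shared no library, 1 inhibitor against Ctrl and another with Enza against Enza, gave 317 higher (148.5 by chance) and 191 lower (76.8) with 118 opposite for NU7441 and CC-115, 361 (68) and 172 (38) with 15 for NU7441 and CC-223, 33 (14.1) and 20 (9.4) with 17 for CC-115 and NU7441, 1919 (821.7) and 2164 (889.7) with 492 for CC-115 and CC-223, 42 (6.6) and 25 (3.9) with 3 for CC-223 and NU7441, and 1737 (842) and 1967 (754.8) with 506 for CC-223 and CC-115. For the same compound with and without Enza they were 37 (1.2) and 17 (0.4) with 0 opposite for NU7441, 4821 (1795.6) and 5103 (1797) with 96 for CC-115, and 1663 (385.3) and 1725 (373.7) with 24 for CC-223. Genes are not independent replicates, so the excess over chance carries no p here.

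**Figure D3:**
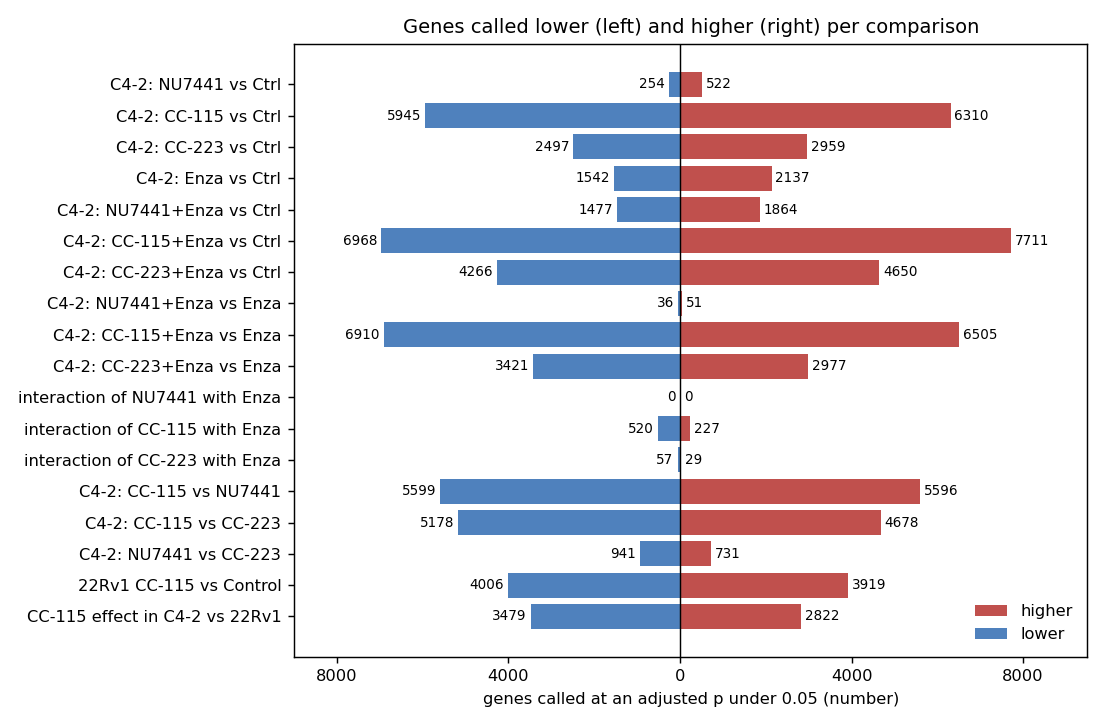
Number of genes called at an adjusted p under 0.05 (horizontal axis) as lower (left) and higher (right) in each comparison. CC-115+Enza against Ctrl has the most, 7711 higher and 6968 lower, and the interaction of NU7441 with Enza has 0.

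Enza against Ctrl asked what the antiandrogen did alone. Of 30 androgen response genes 27 fell and 29 fell adjusted over the list alone, with a median of −1.56 (camera adjusted p = 3.35e-51, and 3.55e-07 with an estimated correlation). CHRNA2 (−3.95 ± 0.21), MAF (−3.41 ± 0.14), SLC45A3 or prostein (ENSG00000158715, chromosome 1, 205626979 to 205649587, −3.34 ± 0.12) and the prostaglandin dehydrogenase HPGD (−3.30 ± 0.24) fell most in that list, and KLK3 fell by 1.59 ± 0.12 (adjusted p = 1.39e-10). CCDC141 (ENSG00000163492, −6.0 ± 0.30) and DOCK8 (−3.54 ± 0.26) fell outside it. Of 6 androgen-repressed genes 4 rose (median 0.74, camera adjusted p = 0.055), among them OPRK1 (2.19 ± 0.43) and UGT2B15 (1.55 ± 0.17). GC, the vitamin D-binding protein (2.99 ± 0.18), LRRC31 (2.96 ± 0.22), the cholesterol exporter ABCA1 (2.93 ± 0.19), GLP1R (2.39 ± 0.24), CAMK2N1 (2.37 ± 0.12), the phospholipase PLD1 (2.33 ± 0.14) and WNT5A (2.02 ± 0.13) rose. PRKDC was not called (−0.14 ± 0.10, adjusted p = 0.38), and MTOR stood at −0.33 ± 0.10 (adjusted p = 0.022) but at 0.0518 without Ctrl 1 and 0.0515 without Enza 2. IGF1R (−1.59 ± 0.21) and IRS1 (−0.62 ± 0.11) fell. Of 26 ATF4 genes 9 rose (camera adjusted p = 0.0119, adjusted p = 0.865 with an estimated correlation), and of 21 sterol genes 5 fell and 1 rose (camera adjusted p = 0.0202, adjusted p = 0.865 with an estimated correlation).

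In all, 2137 genes rose and 1542 fell with Enza. Falls outnumbered rises in some other fits. Among these the rises and falls were 1780 and 1800 with median-of-ratios size factors and 1922 and 2190 with DESeq2. They were 1325 and 1946 without Ctrl 3 and 2228 and 2710 without Enza 1 and CC-115+Enza 1. Rises stayed the majority with no filter (2053 and 1763), a stricter filter (2152 and 2109) and a replicate block (1797 and 1368). They also did without Enza 2 (2646 and 2352) or Enza 3 (2443 and 2300). The total of 3679 became 1808 without Ctrl 1, 2189 without Enza 1 and 1053 in a fit of only these 6 libraries. Enza 1 held 0.124% of its counts in mitochondrial mRNA, against 0.612% and 0.738% in the other Enza libraries, and Enza 3 held 5.37% in mitochondrial rRNA.

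The combinations were then set against Ctrl. With NU7441+Enza 28 of 30 androgen response genes fell (median −1.46, camera adjusted p = 3.84e-52, and 3.12e-07 with an estimated correlation), with CHRNA2 at −4.46 ± 0.22, HPGD at −3.40 ± 0.24 and KLK3 at −1.68 ± 0.12. CCDC141 (−6.48 ± 0.30) and DOCK8 (−4.02 ± 0.27) fell, and PLD1 (2.65 ± 0.14), AMIGO2 (2.55 ± 0.19) and LRRC31 (2.45 ± 0.22) rose. MTOR fell (−0.41 ± 0.10, adjusted p = 0.00401), and PRKDC was not called (−0.16 ± 0.10, 0.347). Of 31 replication genes 4 fell and 9 fell adjusted over the list alone (median −0.31, adjusted p = 0.525 with an estimated correlation), with CLSPN at −0.71 ± 0.13. Of 12 FOXO genes 6 rose and 2 fell (camera adjusted p = 0.108), with PIK3IP1 at 1.10 ± 0.17. In all, 1864 genes rose and 1477 fell, or 55.8% and, with small and mitochondrial RNA removed, 45.4% rises. The total of 3341 became 2155 without Ctrl 1, 7890 in a fit of only these 6 libraries and 7783 without Enza 1 and CC-115+Enza 1.

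With CC-115+Enza 25 of 30 androgen response genes fell (median −1.40, camera adjusted p = 1.86e-11, and 0.00435 with an estimated correlation), with HPGD at −6.55 ± 0.33, MAF at −4.99 ± 0.16, CHRNA2 at −4.88 ± 0.22 and KLK3 at −0.55 ± 0.11. Outside the list CCDC141 (−7.75 ± 0.34) and MAP2K6 (−6.46 ± 0.16) fell most and DMGDH (5.02 ± 0.18), TCP11L2 (4.66 ± 0.23) and CNTN5 (4.65 ± 0.26) rose most. All 31 replication genes fell (median −2.78, adjusted p = 0.287 with an estimated correlation), with CLSPN at −5.03 ± 0.16. Of 11 fatty acid genes 7 rose and 2 fell (median 0.50, camera adjusted p = 0.125), with fatty acid synthase FASN at 2.10 ± 0.20 and SCD at 2.07 ± 0.12. Of 21 sterol genes 10 rose and 3 fell (median 0.44, camera adjusted p = 0.195). Of 18 oxidative phosphorylation genes 17 fell (median −0.97, adjusted p = 0.389 with an estimated correlation). PRKDC fell (−0.41 ± 0.10, adjusted p = 0.00127) and MTOR was not called (−0.12 ± 0.10, adjusted p = 0.264). In all, 7711 genes rose and 6968 fell. CC-115+Enza 1 held 4.78% of its counts on lincRNA, against 2.22% and 2.42% in the other libraries of its group.

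With CC-223+Enza 26 of 30 androgen response genes fell (median −1.22, camera adjusted p = 1.64e-24, and 5.08e-05 with an estimated correlation), with CHRNA2 at −4.11 ± 0.21 and KLK3 at −0.78 ± 0.11, and 5 of 6 androgen-repressed genes rose (camera adjusted p = 0.00573, adjusted p = 0.139 with an estimated correlation), with OPRK1 at 3.29 ± 0.38. All 31 replication genes (median −0.90, adjusted p = 0.138 with an estimated correlation) and all 25 mitosis genes (median −1.14, adjusted p = 0.139 with an estimated correlation) fell. Of 21 sterol genes 17 fell (median −0.72, adjusted p = 0.113 with an estimated correlation), with INSIG1 at −1.37 ± 0.14. Of 11 fatty acid genes 9 fell and 1 rose (median −0.49, adjusted p = 0.113 with an estimated correlation). TCP11L2 (3.18 ± 0.23), ABCA1 (3.18 ± 0.19) and LRRN1 (3.05 ± 0.17) rose most, and CCDC141 (−5.43 ± 0.27) and HPGD (−3.97 ± 0.25) fell. PRKDC was not called (−0.21 ± 0.10, adjusted p = 0.117, but 0.0494 without Ctrl 2) and MTOR fell (−0.53 ± 0.10, adjusted p = 9.95e-05). In all, 4650 genes rose and 4266 fell.

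Each combination was also set against Enza, which shows what the inhibitor added in its presence. CC-115 in the presence of Enza lowered all 31 replication genes (median −2.85, camera adjusted p = 1.42e-21, adjusted p = 0.212 with an estimated correlation), all 16 homologous recombination genes (median −1.49, adjusted p = 0.212 with an estimated correlation) and all 18 oxidative phosphorylation genes (median −0.92, adjusted p = 0.46 with an estimated correlation). Androgen response genes went both ways, 11 up and 12 down of 30 (camera adjusted p = 0.82, the median of −0.06 and the test differed in sign), with KLK2 at 2.20 ± 0.13, KLK3 at 1.05 ± 0.12, HPGD at −3.25 ± 0.51 and MAF at −1.58 ± 0.20. Of 21 sterol genes 14 rose and 3 fell (median 0.61, camera adjusted p = 0.0104, adjusted p = 0.507 with an estimated correlation), with the diphosphomevalonate decarboxylase MVD at 1.47 ± 0.20, and SCD rose by 2.44 ± 0.12. PTPRB (4.28 ± 0.13), TCP11L2 (4.0 ± 0.22) and DMGDH (3.96 ± 0.17) rose most and MAP2K6 (−6.15 ± 0.16), HTR3A (−5.34 ± 0.32) and APLN (−5.18 ± 0.19) fell most. PRKDC stood at −0.27 ± 0.10 (adjusted p = 0.0266, but 0.107 without Enza 1, 0.0507 without Enza 2, 0.154 without Enza 3 and 0.113 without CC-115+Enza 3) and MTOR was not called (0.20 ± 0.10, 0.0751), though it was without Enza 1 (0.32, 0.00736) or CC-115+Enza 1 (0.29, 0.00275). In all, 6505 genes rose and 6910 fell. The total of 13415 was 8115 in a fit of only these 6 libraries.

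CC-223 in the presence of Enza lowered 25 of 26 ATF4 genes (median −0.80, camera adjusted p = 1.02e-18, adjusted p = 0.0221 with an estimated correlation), with CHAC1 at −1.70 ± 0.16 and TRIB3 at −1.43 ± 0.13, and 30 of 31 replication genes (median −0.81, adjusted p = 0.105 with an estimated correlation), with TK1 at −1.39 ± 0.16. Of 11 fatty acid genes 9 fell and 1 rose (median −0.52, adjusted p = 0.0221 with an estimated correlation), and of 21 sterol genes 13 fell (median −0.71, adjusted p = 0.105 with an estimated correlation). Androgen response genes rose in 14 and fell in 5 of 30 (median 0.29, camera adjusted p = 0.000185, adjusted p = 0.0916 with an estimated correlation), with the channel TRPM8 at 0.97 ± 0.11 and KLK3 at 0.82 ± 0.12. MTOR (−0.20 ± 0.10, adjusted p = 0.12, but 0.0356 without Enza 3) and PRKDC (−0.07 ± 0.10, 0.669) were not called. TCP11L2 (2.53 ± 0.22), ZMAT1 (2.17 ± 0.23) and ATP8A1 (2.07 ± 0.15) rose most, and the lipase LIPG (−2.24 ± 0.14), UGT2B11 (−2.03 ± 0.18) and GC (−1.92 ± 0.16) fell most. Of 12 FOXO genes 8 rose (median 0.53, adjusted p = 0.0221 with an estimated correlation). In all, 2977 genes rose and 3421 fell. The total of 6398 was 3863 in a fit of only these 6 libraries.

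NU7441 in the presence of Enza gave 51 rises and 36 falls. GC (−1.03 ± 0.16, adjusted p = 0.00602), ACTA2 (−0.95 ± 0.15, 0.00602) and UGT2B11 (−0.95 ± 0.17, 0.0108) fell, and KLHL24 (0.90 ± 0.19, 0.037), CAMK2B (0.90 ± 0.20, 0.0427) and ATP8A1 (0.87 ± 0.15, 0.00714) rose. KLK3 (−0.09 ± 0.11, 0.764), MTOR (−0.08 ± 0.10, 0.722) and PRKDC (−0.02 ± 0.10, 0.948) were not called. Of 26 ATF4 genes 5 fell and 9 fell adjusted over the list alone (median −0.21, camera adjusted p = 2.77e-07, adjusted p = 0.318 with an estimated correlation), with CHAC1 at −0.84 ± 0.15. No sterol gene was called, and 9 of 21 rose adjusted over the list alone (adjusted p = 0.405 with an estimated correlation). The count of 87 was 0, 12 and 12 without NU7441+Enza 1, 2 and 3, 39, 653 and 1173 without Enza 1, 2 and 3, and 598 without Enza 1 and CC-115+Enza 1. Without NU7441+Enza 1 none of these genes was called, with adjusted p = 0.0511 for CHAC1, GC, ACTA2 and UGT2B11, 0.0523 for ATP8A1 and 0.269 for KLHL24 and CAMK2B. Calls also ended without NU7441+Enza 2 for UGT2B11 (adjusted p = 0.103) and ATP8A1 (0.0517) and without NU7441+Enza 3 for CHAC1 (0.107). The call of KLHL24 ended at adjusted p = 0.131 without NU7441+Enza 2, 0.107 without NU7441+Enza 3 and 0.134 without Enza 1, and that of CAMK2B at 0.131 without NU7441+Enza 2, 0.183 without NU7441+Enza 3 and 0.0693 without Enza 2. A fit of only these 6 libraries called 0, DESeq2 334, no filter 619 and a stricter filter 148. Most calls were falls without Enza 2 (165 rises and 488 falls), without Enza 3 (282 and 891) and with no filter (162 and 457). Most were rises with a stricter filter (93 and 55) and without Enza 1 and CC-115+Enza 1 (422 and 176).

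The interaction asked where an inhibitor acted differently with Enza than without. For CC-115, sterol synthesis genes were higher than the separate effects add up to in 12 of 21 and lower in 1 (14 higher adjusted over the list alone, median 0.66, camera adjusted p = 3.93e-12, adjusted p = 0.0589 with an estimated correlation), with INSIG1, a regulator of sterol synthesis (ENSG00000186480, 1.38 ± 0.19), DHCR7 (0.95 ± 0.13) and MSMO1 (1.01 ± 0.20). Fatty acid genes were higher in 4 of 11 (9 adjusted over the list alone, median 0.58, camera adjusted p = 4.8e-10, adjusted p = 0.00355 with an estimated correlation), with SCD (ENSG00000099194, chromosome 10, 102106881 to 102124591) at 1.79 ± 0.16. Androgen response genes were lower in 13 of 30 and higher in 1 (median −0.36, camera adjusted p = 3.66e-09, adjusted p = 0.00707 with an estimated correlation), with HPGD at −3.90 ± 0.53 and MAF at −2.45 ± 0.23. The cytokine gene TNFSF15 (2.73 ± 0.13), BACE2 (2.07 ± 0.36) and the coactivator WWTR1 (1.82 ± 0.34) were higher and the kinase SGK1 (−3.37 ± 0.24) and WNT5A (−2.56 ± 0.18) were lower. MTOR was lower (−0.66 ± 0.14, adjusted p = 0.00563), and PRKDC (0.27 ± 0.15, 0.336) and KLK3 (−0.13 ± 0.16, 0.708) were not called. In all, 227 genes were higher and 520 lower. The share that was higher, 30.4%, was 49.1% and 49.2% without Ctrl 2 and 3 and 49.4% in a fit of only the 4 groups, which called 166 genes. The total of 747 was 460, 442 and 445 without Ctrl 1, 2 and 3, 468, 388 and 409 without CC-115 1, 2 and 3, 1250 without Enza 3 and 1425 without Enza 1 and CC-115+Enza 1.

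For CC-223, androgen response genes were lower than the separate effects add up to in 8 of 30 and in 18 adjusted over the list alone (median −0.51, camera adjusted p = 4.25e-16, adjusted p = 0.000624 with an estimated correlation), with STEAP4 at −1.79 ± 0.38 (adjusted p = 0.0268) and NDRG1 at −1.67 ± 0.16. The call of STEAP4 ended at adjusted p = 0.0855 without Ctrl 2, 0.0878 without Ctrl 3, 0.077 without CC-223 1, 0.0879 without CC-223 2, 0.174 without Enza 2, 0.0634 without Enza 3, 0.106 without CC-223+Enza 1 and 0.0847 without CC-223+Enza 3. Androgen-repressed genes were higher in 2 of 6 (median 0.81, adjusted p = 0.0212 with an estimated correlation), with UGT2B17 at 1.65 ± 0.28 and MET at 1.10 ± 0.18. NPNT (1.79 ± 0.23) and PLD1 (1.47 ± 0.21) were higher, and SGK1 (−2.09 ± 0.22) and CSGALNACT1 (−1.73 ± 0.19) lower. MTOR (−0.48 ± 0.14, adjusted p = 0.172), PRKDC (0.12 ± 0.15, 0.795) and KLK3 (0.06 ± 0.16, 0.917) were not called. In all, 29 genes were higher and 57 lower, or 33.7% higher, a share of 44.4% with median-of-ratios size factors and 51.1% with small and mitochondrial RNA removed. The total of 86 was 56 and 53 without Ctrl 1 and 2, 55, 52 and 52 without CC-223 1, 2 and 3, 51, 47 and 51 without CC-223+Enza 1, 2 and 3, 191 with DESeq2, 201 with no filter, 134 with a stricter filter, and 444 without Enza 1 and CC-115+Enza 1.

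For NU7441 no gene was called by edgeR in the main fit. At an unadjusted p under 0.05 there were 1548 genes, and DESeq2 called 0. With no filter 23 were called, and 3 without Enza 1 and CC-115+Enza 1. KLK3 stood at −0.34 ± 0.16 (adjusted p = 0.692), PRKDC at 0.10 ± 0.15 (0.846) and MTOR at −0.09 ± 0.14 (0.854). The 25 mitosis genes had a median of 0.48 (camera adjusted p = 1.56e-10, adjusted p = 0.858 with an estimated correlation).

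Set against the inhibitor alone, Enza lowered androgen response genes with every inhibitor. The numbers that fell of 30 were 27 with NU7441 (median −1.42), 30 with CC-115 (median −1.88) and 30 with CC-223 (median −2.10), with adjusted p = 1.14e-08, 4.09e-07 and 2.74e-08 with an estimated correlation. KLK3 stood at −1.94, −1.73 and −1.53 against the respective inhibitor, and MTOR at −0.42, −0.98 and −0.81. PRKDC was not called with any inhibitor (adjusted p = 0.954, 0.343 and 0.959). CCDC141 fell most with each (−5.22, −7.20 and −6.04), followed by CHRNA2 (−3.90) and SLC45A3 (−3.45) with NU7441, HPGD (−7.20) and MAF (−5.86) with CC-115, and CHRNA2 (−5.33) and MAF (−4.82) with CC-223. The largest rises were LRRC31 (3.27), GC (2.58) and ABCA1 (2.54) with NU7441, GLP1R (3.35), CAMK2N1 (3.35) and TNFSF15 (3.24) with CC-115, and LRRC31 (4.48), PLD1 (3.80) and CAMK2N1 (3.19) with CC-223. With CC-115, 9 of 11 fatty acid genes rose on adding Enza (median 0.81, adjusted p = 0.00494 with an estimated correlation) and 13 of 21 sterol genes rose and 1 fell (median 0.50, adjusted p = 0.406 with an estimated correlation). The counts of rises and falls were 629 and 760 with NU7441, 2666 and 2785 with CC-115, and 1293 and 1546 with CC-223. Without Enza 1 and CC-115+Enza 1 they were 1701 and 1931, 2505 and 2973, and 2743 and 3402.

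**Figure D4:**
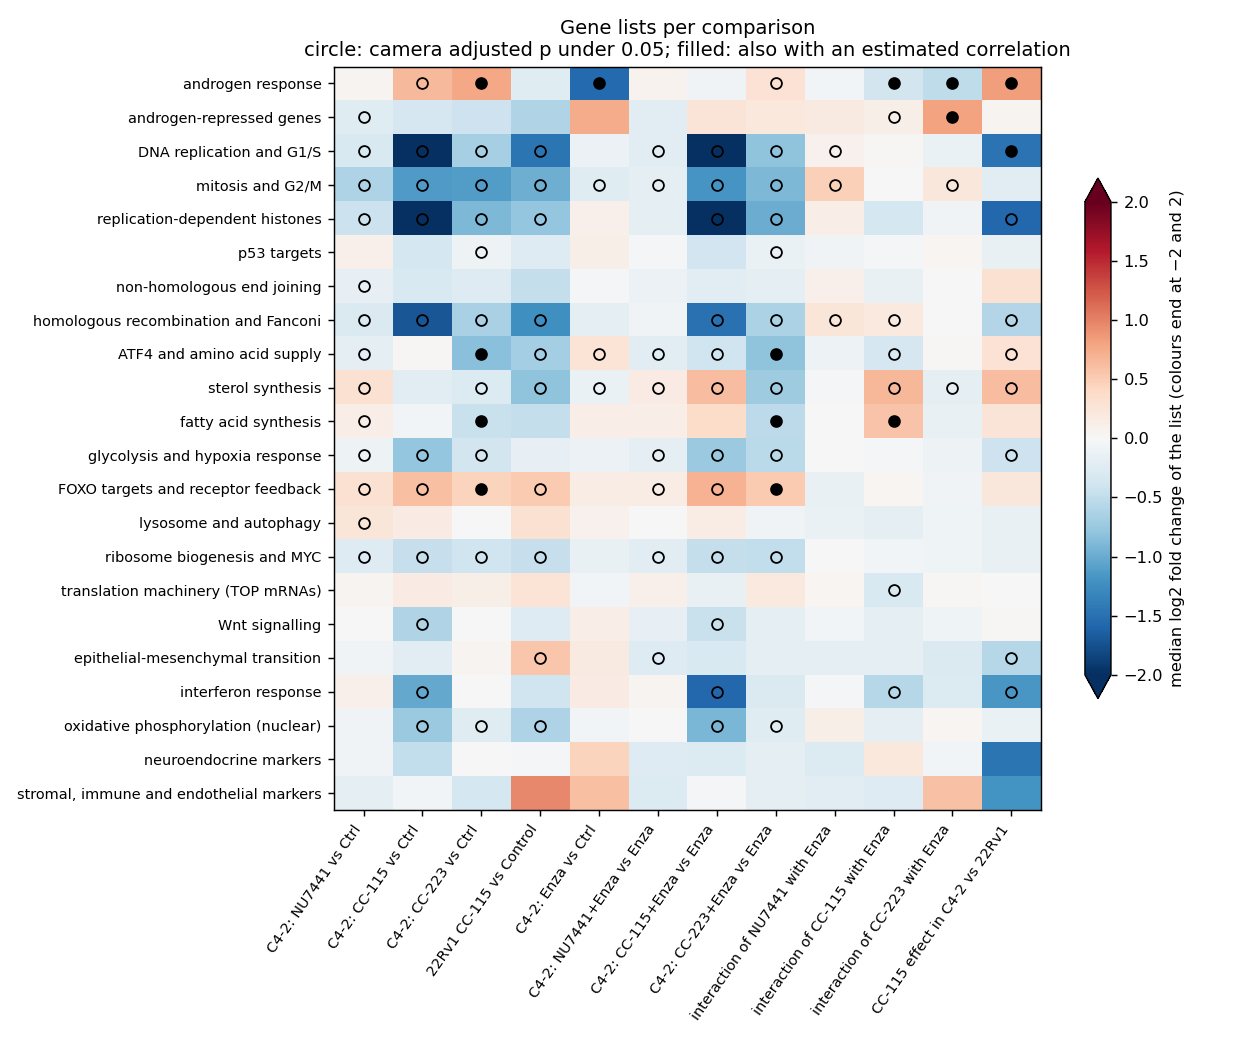
Median log2 fold change (colour, ending at −2 and 2) of each gene list (vertical axis) in 12 comparisons (horizontal axis); circles mark a camera adjusted p under 0.05 and filled circles mark lists that were also called with an estimated correlation. Among the filled circles, androgen response stands at −1.56 with Enza and at 0.78 with CC-223.

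CC-115 in 22Rv1 asked what the compound did in another line. Of 31 replication genes 30 fell (median −1.45, camera adjusted p = 7.57e-13, adjusted p = 0.12 with an estimated correlation), with CLSPN at −2.64 ± 0.23, MCM10 at −2.41 ± 0.14 and MCM6 at −2.26 ± 0.15 (n = 3 Control and 2 CC-115 libraries), and the licensing factor CDT1 rose (1.55 ± 0.15). PRKDC fell by 1.34 ± 0.12 (adjusted p = 0.000261), while KLK3 was not called (0.28 ± 0.13, adjusted p = 0.107). MTOR stood at 0.46 ± 0.13 (adjusted p = 0.0201) with a call that ended at adjusted p = 0.0864 without Control 1, 0.0969 without Control 2 and 0.0871 without CC-115 2. Of 29 androgen response genes 4 rose, with KLK2 at 1.73 ± 0.11, and 8 fell, with FKBP5 at −1.33 ± 0.14 (camera adjusted p = 0.239). Of 25 mitosis genes 20 fell (median −0.98, adjusted p = 0.262 with an estimated correlation), and of 16 homologous recombination genes 13 fell (median −1.22, adjusted p = 0.262 with an estimated correlation), with the helicase BLM at −2.18 ± 0.31. Of 21 sterol genes 13 fell and 2 rose (median −0.80, camera adjusted p = 0.0023, adjusted p = 0.262 with an estimated correlation). Of 26 ATF4 genes 15 fell and 4 rose (camera adjusted p = 0.00649, adjusted p = 0.262 with an estimated correlation), with CHAC1 at −2.47 ± 0.20 and PSAT1 at −2.37 ± 0.16.

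Other 22Rv1 lists moved as well. Of 14 epithelial-mesenchymal genes 7 rose and 1 fell (median 0.55, camera adjusted p = 0.0129, adjusted p = 0.262 with an estimated correlation), with CCN2 at 2.69 ± 0.17 and fibronectin FN1 at 2.32 ± 0.15. Of 18 oxidative phosphorylation genes 14 fell (median −0.62, adjusted p = 0.262 with an estimated correlation), with CYCS at −2.34 ± 0.32. PPP1R15A, a stress-induced phosphatase subunit (ENSG00000087074, 3.03 ± 0.16), ADAMTSL2 (4.07 ± 0.31), PCSK4 (3.58 ± 0.30), WASHC1 (3.21 ± 0.23), TTC16 (3.09 ± 0.27) and tropomyosin TPM2 (3.17 ± 0.30) rose, and the branched-chain aminotransferase BCAT1 (ENSG00000060982, −3.49 ± 0.40), DDC (−3.43 ± 0.25), TIGAR (−3.11 ± 0.36), the transferrin receptor TFRC (−2.89 ± 0.23), CHAC2 (−2.85 ± 0.45) and the glycine decarboxylase GLDC (−2.76 ± 0.27) fell. In all, 3919 genes rose and 4006 fell among 19392 tested. The total of 7925 was 4902 without Control 1, 5129 without Control 2 and 5035 without CC-115 2, and with a term for the shallower libraries, Control 3 and CC-115 2, 5555 rose and 6174 fell.

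The CC-115 effect was compared between the lines by an interaction. Each line had its own table, so cell line and table cannot be told apart. Androgen response genes were higher in C4-2 in 18 of 30 and lower in 3 (median difference 0.83, camera adjusted p = 3.51e-07, adjusted p = 0.0484 with an estimated correlation), with MAF at 2.24 ± 0.49 and KLK3 at 0.85 ± 0.09. MAF held 7 to 37 counts in 22Rv1 Control. Replication genes were lower in C4-2 in 26 of 31 (median −1.48, camera adjusted p = 4.2e-16, adjusted p = 0.0484 with an estimated correlation), with E2F2 at −3.05 ± 0.18 and E2F1 at −2.72 ± 0.15. PRKDC fell less in C4-2 (0.75 ± 0.10), and MTOR differed by 0.34 ± 0.12 (adjusted p = 0.0459). The call of MTOR ended at adjusted p = 0.0812 without C4-2 Ctrl 1, 0.0829 without C4-2 Ctrl 2, 0.0829 without C4-2 Ctrl 3, 0.091 without C4-2 CC-115 2, 0.114 without C4-2 CC-115 3, 0.0708 without 22Rv1 Control 1, 0.0832 without 22Rv1 Control 3 and 0.0902 without 22Rv1 CC-115 1. Sterol genes were higher in C4-2 in 10 of 21 and lower in 1 (median 0.62, adjusted p = 0.115 with an estimated correlation), with SC5D at 1.92 ± 0.41 and STARD4 at 1.80 ± 0.44. In all, 2822 genes were higher and 3479 lower in C4-2. Of 17773 genes tested in both lines, 2351 rose in both (1094.9 by chance), 2698 fell in both (1151.7) and 444 were called in opposite directions, with a correlation of fold changes across genes of 0.599.

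**Figure D5:**
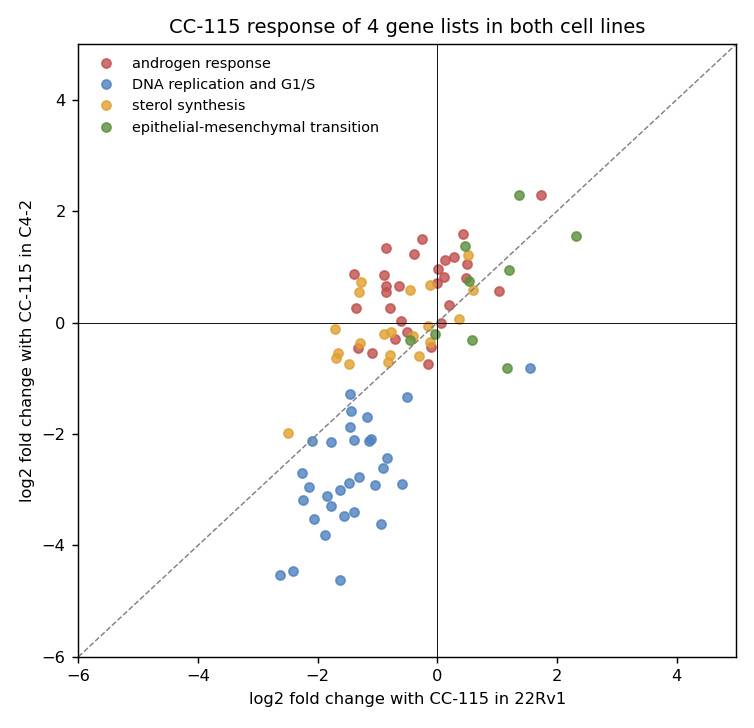
Log2 fold change with CC-115 in 22Rv1 (horizontal axis) and in C4-2 (vertical axis) of the members of 4 gene lists; the dashed line marks equal values. The replication genes have a median of −1.45 in 22Rv1 and −2.89 in C4-2.

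Some named genes share sequence or position with others. POPDC2 overlaps COX17 on the same strand, which had 26.1 times its mean level in C4-2, CCDC141 overlaps TTN (9.35 times) and EGLN3 overlaps SPTSSA (3.56 times). On the other strand ZMYND12 overlaps PPCS (23.5 times), TCP11L2 overlaps CKAP4 (13.2 times) and DDIT3 overlaps MARS1 (6.22 times), and TTC16, RAD54L, NPNT, ACTA2, RPP25 and LRRN1 also overlap a gene with a higher level. The UGT2B genes are paralogs. The strand setting and how shared reads were assigned are not given in the sources used here. Nothing in the labels says that replicates were separate cultures, so every p here measures only the spread between these libraries, which may be technical.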

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

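The CC-115 effect on androgen response genes was higher in C4-2 than in 22Rv1, and that on replication genes was lower. Each result here is a difference of the CC-115 effect between the cell lines, C4-2 minus 22Rv1, that passed the test of an interaction (edgeR for genes, camera for lists, n = 3 and 3 libraries in C4-2 and 3 and 2 in 22Rv1). All tests weighed in this part were chosen before their result was seen, and the term for the shallower libraries was chosen after the libraries were seen. In all, 6301 genes differed, and 4891 to 8388 when 1 library was left out.

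The medians of the lists were 0.83 for androgen response, −1.48 for replication, −1.57 for histones, −0.58 for homologous recombination, 0.29 for ATF4, 0.62 for sterol synthesis, −0.41 for glycolysis, −0.56 for the epithelial-mesenchymal list and −1.16 for interferon response. With an estimated correlation the androgen and replication lists were called (adjusted p = 0.0484 for each), and the others were not (adjusted p = 0.207 for histones, 0.433 for homologous recombination, 0.0864 for ATF4, 0.115 for sterol synthesis, 0.0864 for glycolysis, 0.115 for the epithelial-mesenchymal list and 0.207 for interferon response). Without members that had a group with every library at 0, the medians were 0.82 for androgen response, −1.65 for histones, −0.56 for the epithelial-mesenchymal list and −1.11 for interferon response.

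Among single genes the differences were 0.85 for KLK3, 0.75 for PRKDC, 0.34 for MTOR, 2.24 for MAF, 2.14 for STEAP4, −3.05 for E2F2, −2.72 for E2F1, −2.78 for H1-5, −1.42 for RAD54L and −1.18 for EXO1. In metabolic and stress lists they were 1.68 for EPRS1, 1.5 for SLC7A11, 1.92 for SC5D, 1.80 for STARD4, −1.59 for EGLN3 and −1.43 for PFKP. The interferon genes OAS1 (−2.76) and ISG15 (−1.43) and the matrix genes SPARC (−7.36) and CCN2 (−5.00) were lower in C4-2. Without 22Rv1 CC-115 1 OAS1 stood at −2.47 (adjusted p = 0.0882) and SPARC at −3.14 (0.265), where SPARC held 51 counts against 1 in 22Rv1 CC-115 2. CCN2 held 1, 2 and 3 counts in C4-2 Ctrl and 0, 0 and 1 with CC-115, so its value depends in part on the prior count, and OAS1 held 2, 2 and 1 counts with CC-115 in C4-2. MAF held 21, 37 and 7 counts in 22Rv1 Control and 9 and 5 with CC-115, and STEAP4 14, 24, 18 and 9, 9. MTOR, with an adjusted p of 0.0459, lost its call without any 1 of 8 libraries, as above.

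The largest differences lay in genes almost absent from a line. Fitted values were −8.06 for H2AJ, −6.66 for RPL10L and −5.32 for TMPRSS13, whose 22Rv1 Control libraries all held 0 counts, so these values depend on the prior count and are no bounds. H2AJ held 22 and 0 counts in 22Rv1 CC-115 libraries 1 and 2, RPL10L 12 and 0 and TMPRSS13 4 and 1. Without 22Rv1 CC-115 1 the 3 values were −1.28 (adjusted p = 1) for H2AJ, −0.73 (1) for RPL10L and −4.35 (0.107) for TMPRSS13. H1-3, at 5.07, held 0 counts in each C4-2 Ctrl library and 2, 3 and 4 with CC-115. ZNF619, at 4.64, held 0, 2 and 1 counts in C4-2 Ctrl and 16, 16 and 25 with CC-115. NEGR1, at 4.91, held 5, 2 and 4 counts in C4-2 Ctrl.

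The androgen response difference was weighed against technical explanations. Over the 29 members tested in both lines the medians were 0.66 in C4-2 and −0.25 in 22Rv1, with a median difference of 0.82 (SE 0.17). Each SE of a median here came from 1000 bootstrap draws of the list members and holds no spread between libraries. The difference of the medians was 0.89 with a term for the 2 shallower 22Rv1 libraries. Control and CC-115 each held a shallower library, so the term could move the effect little and does not decide on depth. After a trend over genomic span was taken out the median difference was 0.72 (SE 0.19), which argues against gene length as the whole cause. Over 23 members with at least 10 CPM in the controls of both lines it was 0.65 (SE 0.16), so a part played by genes near the floor in 22Rv1 stays open. Other biological differences between the lines could also play a part, which was not tested. Each line had its own table, so cell line cannot be told apart from any batch that went with the table.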

How the results depend on the processing

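The number of genes called depended on the threshold and the libraries more than on the scaling. The alternatives that left out Enza 1 and CC-115+Enza 1, or added a term for the 2 shallower 22Rv1 libraries, were chosen after the libraries were seen. A count was read as kept within a ratio of 1.5. Of 18 counts, which leave out the 3 comparisons of a combination with its inhibitor alone, 18 were kept with median-of-ratios size factors, 18 with small and mitochondrial RNA removed, 17 with a replicate block, 15 each with DESeq2, no filter and a stricter filter, 7 of 16 with only the groups compared, and 8 of 16 without Enza 1 and CC-115+Enza 1. Both counts with the term for the shallower libraries were kept. Which direction held more genes was less stable: of the 18 counts, only those of CC-115+Enza against Ctrl and of the CC-115 interaction kept the same majority in every alternative, and the NU7441 interaction had none in the main fit. Where a count moved, the cause was not tested unless fewer libraries, fewer genes or a stricter threshold make it by construction.

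A log2 fold change of at least 1, which is stricter by construction, gave 75 genes higher and 40 lower (1.2e+02 of 776 in all) for NU7441, 5305 of 12255 for CC-115, 1078 of 5456 for CC-223 and 949 of 3679 for Enza. It gave 917 of 3341 for NU7441+Enza, 7377 of 14679 for CC-115+Enza and 2567 of 8916 for CC-223+Enza against Ctrl, and 9 of 87, 6052 of 13415 and 1116 of 6398 against Enza. It gave 285 of 747 for the CC-115 and 38 of 86 for the CC-223 interaction, 4273 of 11195 for CC-115 against NU7441, 3364 of 9856 for CC-115 against CC-223, 267 of 1672 for NU7441 against CC-223, 3787 of 7925 in 22Rv1 and 2679 of 6301 between lines. The NU7441 interaction stayed at 0.

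DESeq2 called 1198 genes for NU7441, 334 for NU7441+Enza against Enza and 191 for the CC-223 interaction, and a stricter filter 1287, 148 and 134. With no filter there were 619 for NU7441+Enza against Enza, 23 for the NU7441 and 201 for the CC-223 interaction. With a replicate block, which pairs libraries by number, NU7441+Enza against Enza had 43.

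Fits of only the groups compared called 2706 genes for NU7441, 9382 for CC-223, 1053 for Enza, 7890 for NU7441+Enza against Ctrl, 0, 8115 and 3863 for NU7441+Enza, CC-115+Enza and CC-223+Enza against Enza, 166 for the CC-115 interaction and 4228 for NU7441 against CC-223. Without Enza 1 and CC-115+Enza 1 there were 5011 for NU7441, 9900 for CC-223, 7783 for NU7441+Enza against Ctrl, 598 for NU7441+Enza against Enza, 3, 1425 and 444 for the interactions of NU7441, CC-115 and CC-223, and 5823 for NU7441 against CC-223. In the 3 comparisons of a combination with its inhibitor alone, the counts were 3632 against 1389 in the main fit for NU7441, 5478 against 5451 for CC-115 and 6145 against 2839 for CC-223.

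With 1 library left out, counts ran from 76 (without NU7441 2) to 813 for NU7441, with 162, 254 and 361 without Ctrl 1, 2 and 3. They ran from 1808 (without Ctrl 1) to 4998 for Enza, with 2189 without Enza 1, and from 2155 (without Ctrl 1) to 2809 for NU7441+Enza against Ctrl. For NU7441+Enza against Enza they ran from 0 to 1173, with 0, 12 and 12 without NU7441+Enza 1, 2 and 3 and 39, 653 and 1173 without Enza 1, 2 and 3. For the CC-115 interaction they ran from 388 to 1250, with 460, 442 and 445 without Ctrl 1, 2 and 3, 468, 388 and 409 without CC-115 1, 2 and 3 and 1250 without Enza 3. For the CC-223 interaction they ran from 47 to 117, with 56 and 53 without Ctrl 1 and 2, 55, 52 and 52 without CC-223 1, 2 and 3 and 51, 47 and 51 without CC-223+Enza 1, 2 and 3. For NU7441 against CC-223 they ran from 877 (without NU7441 1) to 1685, with 934 without NU7441 3 and 906, 904 and 959 without CC-223 1, 2 and 3. In 22Rv1 they ran from 4902 (without Control 1) to 8538, with 5129 without Control 2 and 5035 without CC-115 2, where the lone CC-115 library is assumed to vary like the others.

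The other ranges with 1 library left out stayed within the ratio: 11083 to 11500 for CC-115, 3727 to 4972 for CC-223, 13398 to 15029 for CC-115+Enza and 7072 to 8288 for CC-223+Enza against Ctrl, 12629 to 13725 and 4543 to 6886 against Enza, 0 to 0 for the NU7441 interaction, 9913 to 10476 for CC-115 against NU7441, 8433 to 8777 for CC-115 against CC-223 and 4891 to 8388 between lines.

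Among the list tests 186 were called, and 27 with an estimated correlation, which widens the null for lists whose members vary together. With fry 38 list calls were lost and 67 gained, without Enza 1 and CC-115+Enza 1 13 were lost and 25 gained, and with a replicate block 2 were lost and 1 gained. Of the named gene values, 1114 kept their side of the threshold with DESeq2, while 14 lost and 7 gained a call, and 1114 kept it with median-of-ratios size factors, while 21 lost a call. Losses and gains were 526 and 5 over all fits with 1 library left out, 82 and 5 with only the groups compared, 45 and 0 with no filter, 34 and 0 with a replicate block, 14 and 9 without Enza 1 and CC-115+Enza 1, 12 and 1 with small and mitochondrial RNA removed, 3 and 6 with a stricter filter, and 0 and 1 with the term for the shallower libraries. CYP51A1 was the single named gene that reversed, from 0.71 with Enza to −0.05 (adjusted p = 0.837) without Enza 1, in a range of −0.05 to 0.96 with 1 library left out, and −0.01 (0.957) without Enza 1 and CC-115+Enza 1.

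At an adjusted p under 0.01 the genes called on the same side were fewer by construction. Against Ctrl they were 104 higher and 38 lower (1.4e+02 of 558 in all) for NU7441 and CC-115, 158 of 618 for NU7441 and CC-223 and 2399 of 4056 for CC-115 and CC-223. Against Ctrl for the first and Enza for the second compound they were 6 of 54, 127 of 508 and 133 of 533 for NU7441 with NU7441, CC-115 and CC-223, 6 of 53 and 2525 of 4083 for CC-115 with NU7441 and CC-223, and 7 of 67, 2142 of 3704 and 1907 of 3388 for CC-223 with NU7441, CC-115 and CC-223. Between lines they were 2901 of 5049. In simulated data 32.8% of genes changed 1.5-fold were recovered for NU7441 against Ctrl, 13.4% for the CC-115 interaction, 1.49% in 22Rv1 and 2.99% between lines, so most changes of that size were missed.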

Other observations

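Noncoding genes and classes went both ways with CC-115 in C4-2, and no class was tested against other genes. The noncoding genes and classes, the sum of the NU7441 and CC-223 effects and the fit without both libraries that stood apart were chosen as tests after the results were seen. SNHG1 (2.02 ± 0.18, adjusted p = 4.18e-10) and GAS5 (2.17 ± 0.15, 2.97e-12), which host small nucleolar RNAs, were higher with CC-115 by edgeR (n = 3 libraries per group), and with CC-223 they were not called (−0.46, adjusted p = 0.0547 for SNHG1 and 0.10, 0.646 for GAS5). MALAT1 was higher with CC-115 (1.58 ± 0.25, 5.41e-06) and with CC-223 (0.89 ± 0.24, 0.00849). Of 1422 lincRNA genes 470 rose and 175 fell with CC-115, of 2223 antisense genes 509 rose and 264 fell, of 1889 processed pseudogenes 263 rose and 213 fell, of 310 transcribed unprocessed pseudogenes 171 rose and 34 fell, and of 196 snoRNA genes 13 rose and 46 fell. With CC-223, 222 lincRNA genes rose and 50 fell. Among lincRNA genes 89 rose and 42 fell with Enza, and 15 rose and 7 fell with NU7441. Of 14120 protein-coding genes 4218 rose and 4888 fell with CC-115. With CC-115 in 22Rv1, 17 of 154 snoRNA genes rose and 6 fell, and 204 of 925 lincRNA genes rose and 50 fell. The share of counts on 7SK was 3.48 ± 0.0408% in Ctrl (mean ± SD), 4.22 ± 0.561% with NU7441, 5.08 ± 0.205% with CC-115 and 4.92 ± 0.0528% with CC-223, and in 22Rv1 it was 9.85 ± 0.485% in Control and 14.6 ± 0.985% with CC-115.

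The CC-115 effect was set against the sum of the NU7441 and CC-223 effects at the doses given. Replication genes lay below that sum in 27 of 31, with a median of −1.95 (camera adjusted p = 4.52e-20, adjusted p = 0.366 with an estimated correlation), which argues against the plain sum as the whole of the fall. Mitosis genes lay above it in 14 of 25 and below in 1 (median 0.84, adjusted p = 0.679 with an estimated correlation), and ATF4 genes above it in 17 of 26 and below in 1 (median 0.75, adjusted p = 0.366 with an estimated correlation). Androgen response genes lay below it in 17 of 30 and above in 5 (median −0.50, adjusted p = 0.423 with an estimated correlation). In all, 6517 genes differed from the sum. Potency at 1 µM was not measured here, so a stronger block of the same targets by CC-115 may account for it, as may another target, and the −1.95 does not part these.

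Sterol and fatty acid genes lay higher with CC-115 and Enza together than the separate effects add up to. The median was 0.65 over 32 members, with 16 called higher. Its SE of 0.05 came from bootstrap draws of the members and holds no spread between libraries. Without both libraries that stood apart the median was 0.79 with 23 called higher, after a trend over genomic span was taken out it was 0.73, and with median-of-ratios size factors it was 0.66. The median over all genes was −0.055 with TMM and −0.037 with median-of-ratios size factors. These 2 scalings thus differ little, and the 0.66 does not decide on scaling. The other values argue against those 2 libraries and gene length as the whole cause. The other libraries were not left out in this test, and no biological explanation was tested.

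CC-115+Enza 1 stood apart from the other libraries of its group. Its median absolute log2 difference from them was 0.418 over 9839 genes with a mean of at least 10 CPM, against 0.035 to 0.342 for the other 23 libraries, of which Enza 1 was highest, which argues against features near the floor as the whole cause. It was the shallowest of its group, with 31.35 M counts against 42.02 and 44.86 M. With these 2 thinned to its total in 20 draws the difference was 0.403 on average (0.352 to 0.421). Genes with a mean of at least 10 CPM keep many counts after thinning, so this test could change little and does not decide on depth. Its summed CPM of 356 olfactory receptor genes was 30.2, which was 1.63 times the highest of the others (18.6 in CC-223 2), so background from DNA or random transcripts may play a part and stays open. No biological explanation was tested.

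Other splits of the same libraries were fitted for each comparison in C4-2 except those of a combination with its inhibitor alone. For 2 groups of 3 libraries there are 10 splits, too few for a share under 0.05. In each of these comparisons 1 split, the real one, gave the real count or more. A split that mixes the 2 groups moves their difference into the spread, so few calls are expected from it. Such counts do not show how many calls chance gives. The real count and the highest other were 776 and 0 for NU7441, 12255 and 0 for CC-115, 5456 and 0 for CC-223, 3679 and 1 for Enza, 3341 and 0 for NU7441+Enza, 14679 and 0 for CC-115+Enza and 8916 and 0 for CC-223+Enza against Ctrl. Against Enza they were 87 and 0 for NU7441+Enza, 13415 and 1508 for CC-115+Enza and 6398 and 0 for CC-223+Enza. Between compounds they were 11195 and 0 for CC-115 against NU7441, 9856 and 0 for CC-115 against CC-223 and 1672 and 0 for NU7441 against CC-223.

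For the interactions 60 splits of the inhibitor labels were fitted. The real count of the CC-115 interaction, 747, was reached by 8 of 60, with 10831 as the highest other, and that of the CC-223 interaction, 86, by 8 of 60, with 3404 as the highest other, so chance is not excluded by these splits. For NU7441 the real count was 0, which 60 of 60 reached, and the highest other was 542. A split with several times the real count points to a structure of the samples. Here 7 of the 8 splits in each of the CC-115 and CC-223 interactions kept unequal numbers of inhibitor labels in the arms with and without Enza, so that part of the inhibitor effect entered the interaction. Among the 28 splits with equal numbers the highest count was 0 in each of the 3 interactions. Those splits mix libraries with and without the inhibitor, so its effect enters the spread and few calls are expected. Their counts do not show how many calls chance gives.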
